A study of Homo sapiens with 8 samples.

How the data were processed

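RNA was measured in bulk libraries of brain organoids at day 30 from the human line IMR90-4, 3 of control and 3 of FABP7 knockdown organoids, as the labels group them. The labels also list 2 single-cell libraries, 1 per group, which were not analysed here. The labels' protocol, the same text for every sample, describes TrypLE dissociation and a single-cell library kit, so the preparation of the bulk libraries is not separately stated. The knockdown method, strand use, aligner, counting tool and gene annotation are not given in the sources used here, and the genome build was hg38 per the submitters' processing notes.

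The deposited table gave expected counts, FPKM, TPM and a normalized read count per gene and library, per the file headers, for 17504 genes. Of the expected count values in each library 12.6 to 14.9% were not whole numbers, as arises when reads are divided between genes or transcripts. The deposited normalized read count was a signal that equalled the rounded-up count times 1 factor per library, and the authors' group averages of it were rounded up before the factor. The authors' FPKM and their averages entered no test. No column of per-sample values was left without a sample. Genes were matched by NCBI Gene ID to RefSeq on GRCh38.p14, which placed 17495 of them, 17478 protein-coding.

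Expected counts were rounded to whole numbers and tested in R 4.3.3 with edgeR 4.0.16. TMM factors (1.02, 1.03 and 1.03 in control, 0.974, 0.976 and 0.979 in knockdown), the filterByExpr filter (minimum count 10, minimum total 15) and a robust quasi-likelihood F-test were used, with Benjamini-Hochberg adjustment and a threshold of 0.05. All log2 fold changes are knockdown minus control, and CPM values are TMM-scaled means with SD over 3 libraries. Genes with at least 1 count numbered 16213, 16026 and 16075 in control replicates 1, 2 and 3 and 16010, 16006 and 16009 in knockdown. A floor of 3 counts in a library corresponds to 0.188 to 0.217 CPM. For genes with at most 3 counts in a group, ratios carry a 95% interval from the binomial distribution that covers counting error only. The 10 most abundant genes held 5.29 to 5.36% of counts in control and 6.06 to 6.24% in knockdown.

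Fixed lists of genes, 44 in number, were tested against all other genes with camera of limma 3.58.1 at a preset correlation of 0.01 where at least 5 members were tested, which left 38 lists. Camera with an estimated correlation and fry were run beside it. Of 764 list members 20 were absent from the table and 5 were matched by synonym. Counts of members were also adjusted over the list alone. The lists, tests, groups and alternatives were set before the data were examined. The rule for names was also set then: FABP7, the 10 largest rises and 10 largest falls among called genes with a mean of at least 5 CPM and no overlap between groups, up to 4 members of each list by smallest p, members of lists where 5 or fewer changed, the FABP family, and for other cell types the 2 most abundant markers. Other names, which are KIF2C, CDC20, CDCA8, DCX, EPHA3, NDE1, FLNA, CXCL12, NDEL1, VIM, NES, PTPRZ1, HOPX, PPP1R17, NEUROG2, CDH2, LAMB2 and SESN2, were chosen after their values were seen.

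Alternatives were DESeq2 size factors, upper-quartile factors, library totals alone, the DESeq2 1.42.0 Wald test, limma-voom, no low-count filter, a filter of at least 10 CPM in 3 libraries, the replicate number as a block, limma-trend on log2(TPM + 1) for genes of at least 1 TPM in 3 libraries, and leaving out each library in turn. A test against a 1.5-fold change was run with glmTreat. A further 3 were added after the data were seen: leaving out genes of shifted chromosome segments, limma-trend on log2 CPM, and the same after each library's trend with transcript length and GC content was removed by natural splines with 5 degrees of freedom. The gene test and camera were tested on simulated counts with known changes, and the search for chromosome segments on simulated fold changes. With far fewer changed genes than in the data, the gene test recovered 52% at 1.2-fold and 98% at 2-fold, with 9 false calls of 174. Camera called 5 of 5 shifted and 0 of 20 unchanged lists, but genes were drawn independently, so its preset correlation was not checked. The segment search found the 1 shifted block.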

Results

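Bulk RNA sequencing was analysed from brain organoids at day 30, grown from IMR90-4, a line of human induced pluripotent stem cells. The comparison set 3 libraries of FABP7 knockdown organoids against 3 libraries of control organoids, and the series title places it in the study of how FABP7 bears on the radial glial scaffold of the developing human cortex. Per the labels' protocol, each group came from 1 cell line derived from IMR90-4, so a difference between the lines other than FABP7 is not separated from the knockdown. The labels do not say that replicates were separate cultures, and p-values therefore measure only the spread between these libraries, which may be technical. Estimated counts summed to 15675888, 13424959 and 14448632 in control replicates 1, 2 and 3 and to 15063815, 15172264 and 15360145 in knockdown replicates 1, 2 and 3. Log2 CPM correlated across genes at 0.994 to 0.995 within groups and at 0.975 to 0.977 between groups, where genes are not independent replicates. The first principal component held 71.7% of the variance and separated the groups. Replicates within a group differed by more than counting noise (chi-square per degree of freedom of 1.65 to 4.08), so none was a repeat deposit of another.

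FABP7, the brain fatty acid binding protein and a marker of radial glia, was almost lost in the knockdown organoids. The gene (NCBI Gene 2173, chromosome 6, 122749201 to 122784074 on GRCh38) had counts of 3123, 2650 and 2850 in the control libraries and 14, 15 and 16 in the knockdown libraries. Its level fell 189.7-fold, from 193 ± 2.23 to 1.01 ± 0.0547 CPM (SD, n = 3 each), a log2 fold change of -7.57 with a standard error of 0.09 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 6.04e-26). Among its relatives, FABP3, the heart-type protein, fell by 0.89 on the log2 scale from 41.5 ± 2.49 to 22.4 ± 1.95 CPM, and it lies in the part of chromosome 1 described at the end. PMP2, the myelin member of the family, rose by 2.34 from a low 0.307 ± 0.15 to 1.62 ± 0.189 CPM. FABP5 had a log2 fold change of 0.14 (edgeR adjusted p = 0.0474), which was -0.02 on the TPM scale and 0.00 (-0.000291) after removal of the length and GC trend. Its call was lost without control replicate 1 (adjusted p = 0.055), 2 (0.0548) or 3 (0.118) and without knockdown replicate 1 (0.0634) or 2 (0.33). It was also lost under upper-quartile factors (0.111) and library totals (0.326), with at least 10 CPM (0.0869), without segment genes (0.0752) and in the DESeq2 (0.107), limma-voom (0.0519) and limma-trend (0.0527) tests. FABP4 and FABP6 were too low to test.

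The difference between the groups spread over much of the transcriptome but was mostly small. Of 13468 genes tested, 6966 (51.7%) passed an adjusted p of 0.05 in the edgeR quasi-likelihood test, 3557 higher and 3409 lower in knockdown. A change of at least 2-fold was met by 531 genes, 212 higher and 319 lower, and 631 genes passed a test against a 1.5-fold change. The 3 knockdown libraries lay wholly above or below the 3 controls for 57.3% of the tested genes, where chance gives 10%. The biological coefficient of variation, as edgeR names the spread between libraries of a group, was 4.03%, and that spread may be technical. The balance of directions depended on the scaling: 51.1% of the called genes were higher under TMM, 37.7% under library totals alone and 20.6% on log2(TPM + 1), scalings whose median log2 fold change over all genes lay at -0.07 and -0.16.

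The largest rises by ratio included ZNF558 and CHCHD2, which were near silence in control. ZNF558, a zinc finger gene on chromosome 19, had 0 counts in each control library and 759, 743 and 735 in the knockdown libraries, at least 248-fold higher when the controls are set to a floor of 3 counts per library, and it overlaps MBD3L1. CHCHD2, a mitochondrial intermembrane space protein, had 2 counts over the 3 controls against 4391 over the 3 knockdown libraries, a ratio of 2199 with a 95% counting interval of 608 to 18161. CHCHD2 has processed pseudogenes, so its counts are uncertain to the extent that the counting divided reads between copies. Another zinc finger gene, ZNF229, rose from 0.697 ± 0.0252 to 14.8 ± 1.22 CPM, and TXNRD3, a thioredoxin reductase, from 2.5 ± 0.279 to 21.5 ± 1.81 CPM. FGFR3, a fibroblast growth factor receptor of ventricular zone progenitors, rose from 16.9 ± 1.77 to 102.7 ± 3.79 CPM (log2 fold change 2.61 ± 0.07 SE). NR2F1 and NR2F2, the COUP transcription factors that pattern the caudal and ventral forebrain, rose from 8.55 ± 0.735 to 50.5 ± 0.512 CPM and from 5.05 ± 0.532 to 29.7 ± 1.75 CPM. PMEL, a melanosome protein of pigmented cells, rose from 1.96 ± 0.422 to 12.4 ± 0.494 CPM. The uncharacterised LOC110384692 rose from 10.02 ± 1.79 to 116 ± 4.32 CPM but lies within the span of SLC22A23, and FAM72C rose from 5.72 ± 0.878 to 31.9 ± 2.78 CPM but has the near-identical copies FAM72A, FAM72B and FAM72D, so both values are uncertain. Adjusted p in the edgeR test was at most 9.87e-13 for each of these genes. All 3 knockdown libraries lay above all 3 controls, as the rule for naming them required.

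The deepest falls beside FABP7 included another zinc finger gene and targets of p53. ZNF585A had 365, 329 and 360 counts in the controls and 0, 0 and 1 in knockdown, a ratio of 1052 with a 95% counting interval of 188 to 41609, and its paralog ZNF585B had 5 or fewer counts in every library. CDKN1A, which encodes the cell cycle inhibitor p21, fell by 3.04 on the log2 scale from 81.3 ± 7.73 to 9.89 ± 0.798 CPM. PHLDA3, a p53-induced repressor of AKT, fell by 3.01 from 19 ± 1.81 to 2.36 ± 0.571 CPM and also lies in a lowered part of chromosome 1. GNRH1, which encodes gonadotropin-releasing hormone, fell by 2.70 from 77.98 ± 6.29 to 12.05 ± 1.39 CPM, and ZIC4, a cerebellar and midline zinc finger factor, fell by 2.44 from 28.1 ± 0.773 to 5.17 ± 0.637 CPM. DOCK9, an exchange factor for CDC42, dropped by 2.60 from 30.3 ± 1.13 to 4.99 ± 1.05 CPM. SPINK5, a protease inhibitor, SAMSN1, an adaptor protein, and SLCO1A2, an organic anion transporter, fell by 2.97, 2.80 and 2.56, though SLCO1A2 overlaps IAPP and is uncertain for that reason. The edgeR adjusted p was at most 9.35e-12 for each of the genes named by rule. Their 3 knockdown libraries all lay below all 3 controls, as that rule required.

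**Figure D1:**
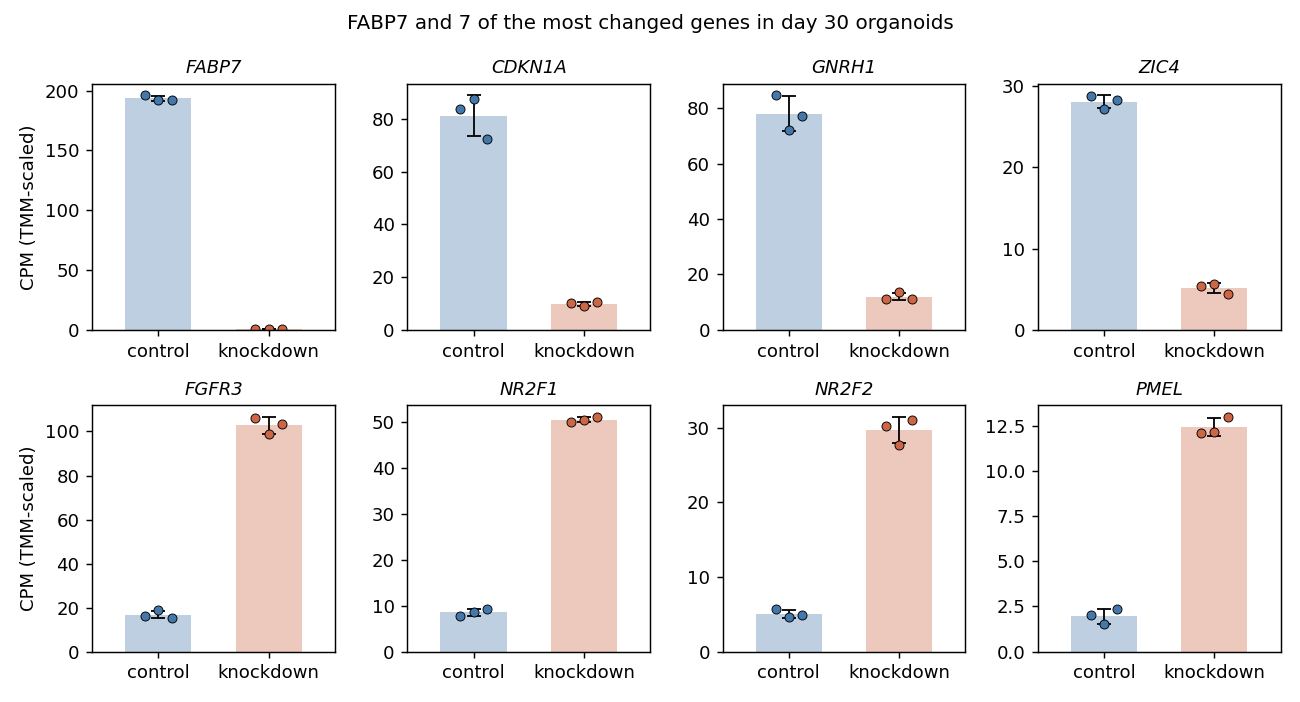
TMM-scaled CPM (vertical axes, linear, starting at 0) of FABP7 and 7 other genes in the control and knockdown groups; points are libraries, bars are means and error bars are SD (n = 3). FABP7 lies at 193 CPM in control and 1.01 CPM in knockdown, CDKN1A, GNRH1 and ZIC4 lie lower in every knockdown library, and FGFR3, NR2F1, NR2F2 and PMEL lie higher.

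Genes of mitosis rose together. In the list of G2/M phase genes, 45 of 48 members were higher and none lower, with a median log2 fold change of 0.87, and 46 were higher when adjusted over the list alone. TOP2A, the DNA topoisomerase of dividing cells, rose from 293 to 648 CPM (log2 fold change 1.14 ± 0.05 SE), CDK1, the mitotic kinase, from 87.8 to 202 CPM, NEK2 from 47.3 to 109 CPM and CKS1B from 55.5 to 122 CPM. KIF2C, CDC20 and CDCA8, named after their values were seen, rose by 0.77, 0.57 and 0.59 although they lie in the lowered part of chromosome 1. The list was higher than other genes in camera (adjusted p = 1.57e-20 with a preset correlation of 0.01, and adjusted p = 0.0528 with an estimated correlation). Genes of G1/S and S phase moved less, with 15 of 39 higher, 5 lower and a median of 0.11 (-0.06 on log2(TPM + 1)), counts that were the same when adjusted over the list alone. DTL rose by 1.00 and GINS2 by 0.50 on the log2 scale, whereas NASP, in the lowered part of chromosome 1, fell by 0.67, and camera did not call the list (adjusted p = 0.216). No list in the set of 38 tested by camera passed 0.05 with an estimated correlation, while 29 passed in fry, which asks whether members move one way on balance and makes no comparison with other genes. For called lists the estimated correlation lay below 0.01 in pan-neuronal (-0.018), migration (-0.00238), p53 (-0.0143), glycolysis (-0.00459), sterol (-0.0201) and Cajal-Retzius genes (-0.133). It lay above 0.01 in G2/M (0.039), synapse and axon (0.057), stress response (0.0333), outer radial glia (0.0898) and interferon genes (0.0468). A higher correlation between members therefore did not cost the lists below 0.01 their calls. With an estimated correlation, camera also takes its p-value from a t distribution on the few residual degrees of freedom of the libraries. With a preset correlation it does not, so a lost call alone does not show that members were correlated.

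Targets of p53 fell. In the list of p53 and apoptosis genes, 15 of 18 members were lower and none higher, with a median of -0.51, and 17 were lower when adjusted over the list alone. After CDKN1A and PHLDA3 the clearest were AEN, an apoptosis-enhancing nuclease, from 52.6 to 14.6 CPM (-1.85 ± 0.08 SE), and ZMAT3, a p53-induced RNA binding protein, from 102 to 42.1 CPM (-1.28 ± 0.05 SE). The list was lower in camera (adjusted p = 3.01e-06, and adjusted p = 0.0528 with an estimated correlation). PHLDA3 is its one member in a shifted chromosome segment, and without genes of those segments the median was -0.48 (camera adjusted p = 3.60e-06).

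Neuronal genes fell. Of 16 pan-neuronal genes, 15 were lower and none higher, the same numbers when adjusted over the list alone, with a median of -0.54. NEFL and NEFM, which encode neurofilament subunits, fell from 312 to 118 CPM (-1.41 ± 0.04 SE) and from 112 to 44.1 CPM (-1.34 ± 0.05 SE). SYT1, a calcium sensor of synaptic vesicles, fell from 242 to 107 CPM and SNAP25, a fusion protein of the presynaptic membrane, from 109 to 53.3 CPM, whereas DCX, a microtubule protein of young neurons and the one member not called, had a log2 fold change of 0.03. The list of synapse and axon genes had 21 of 27 members lower and 1 higher, the same numbers when adjusted over the list alone, with a median of -0.41. GRIA1, an AMPA receptor subunit, fell by 1.06 and CNTN1, an axonal adhesion protein, by 0.78, NFASC fell by 0.83 within a lowered segment of chromosome 1, and the member that rose was EPHA3, an ephrin receptor, by 0.45. Neuronal migration genes had 15 of 25 members lower and 4 higher (16 and 5 when adjusted over the list alone), with a median of -0.24 that was -0.38 on log2(TPM + 1). RELN, the extracellular guide of migrating neurons, fell from 20.5 to 3.98 CPM (-2.36 ± 0.11 SE), with its receptor LRP8 (-0.81, in the lowered part of chromosome 1), its adaptor DAB1 (-1.23) and ROBO1 (-0.72), while the members that rose were NDE1, FLNA, CXCL12 and NDEL1 (0.71, 0.39, 0.79 and 0.12). DAB1 also lies on chromosome 1, within the 5 Mb after that lowered part, where 9 expressed genes had a median of -0.49. In camera these lists were lower than other genes with adjusted p of 1.37e-07 for pan-neuronal, 1.44e-05 for synapse and axon and 0.00698 for migration. The calls were lost with an estimated correlation, at adjusted p = 0.0528, adjusted p = 0.133 and adjusted p = 0.133 with an estimated correlation.

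**Figure D2:**
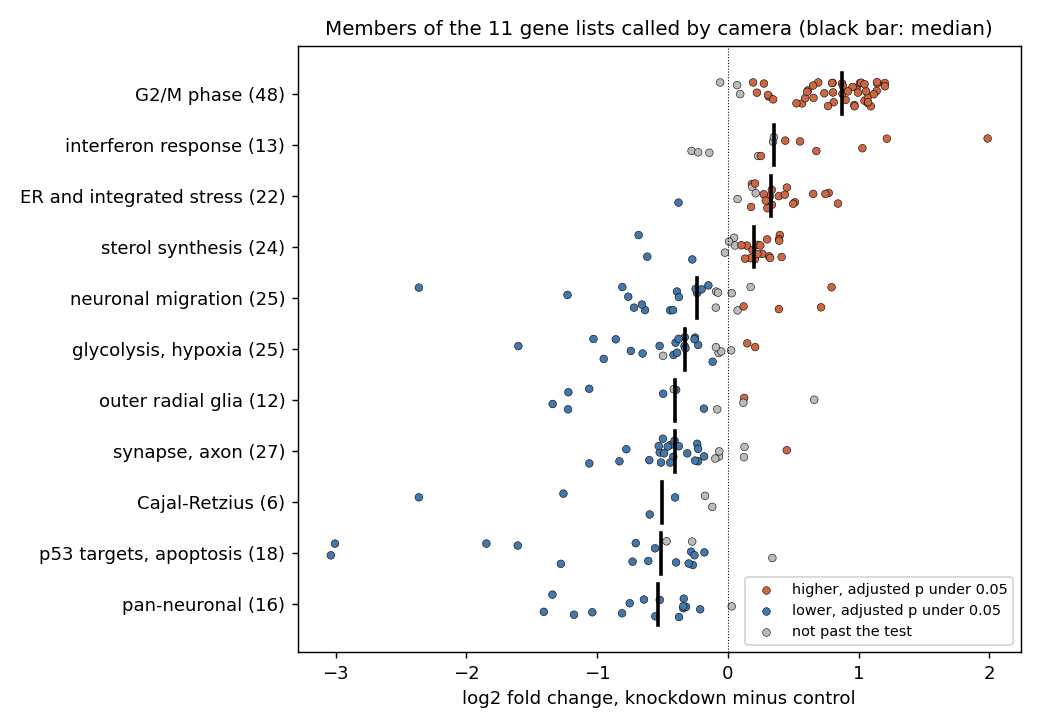
Log2 fold change (horizontal axis, knockdown minus control) of each tested member of the 11 gene lists called by camera, with the number of members in parentheses and the list median as a black bar; orange points were higher, blue points lower and grey points did not pass the edgeR test. The G2/M phase members centre on 0.87 and the pan-neuronal members on -0.54.

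Radial glial genes did not move one way. Of 14 members, 6 were higher and 4 lower, the same numbers when adjusted over the list alone, with a median of 0.07 (0.11 with the length and GC trend removed and -0.12 on log2(TPM + 1)) and no call in camera (adjusted p = 0.517). SOX2, a progenitor transcription factor, rose from 206 to 308 CPM (0.58 ± 0.04 SE) and HES5, a Notch effector in the lowered part of chromosome 1, from 17.4 to 28.1 CPM, whereas SLC1A3, a glial glutamate transporter, fell by 0.39 and PAX6 by 0.25. VIM and NES, intermediate filament genes of the radial fibre named after their values were seen, each had a log2 fold change of -0.10. Genes of the outer radial glia list fell, with 7 of 12 lower and 1 higher (7 and 2 when adjusted over the list alone) and a median of -0.41. Bulk libraries do not show which cells expressed them, and ETV5 is also among the fibroblast growth factor and ERK targets described later. ETV5, a transcription factor downstream of fibroblast growth factor, fell from 31.1 to 12.3 CPM, MOXD1 from 35.4 to 15.2 CPM, TNC, the matrix protein tenascin C, from 22.7 to 10.9 CPM and TKTL1 by 0.50, while the member that rose was PTPRZ1, by 0.12. HOPX, named after its values were seen, had a log2 fold change of 0.66 at 0.957 and 1.53 CPM (edgeR adjusted p = 0.0515). Camera called this list lower at adjusted p = 0.0196, and the call was lost at adjusted p = 0.362 with an estimated correlation, without control replicate 3 (adjusted p = 0.0751) and on log2(TPM + 1) (adjusted p = 0.0594). Intermediate progenitor genes had 2 of 10 members higher (HES6 and EOMES) and 4 lower (BTG2, INSM1, PPP1R17 and NEUROG2), the same numbers when adjusted over the list alone. BTG2, an antiproliferative gene in a lowered segment of chromosome 1, fell by 0.97 and INSM1 by 0.30, HES6 rose by 0.38, and camera did not call the list (adjusted p = 0.397).

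Genes of the list for Cajal-Retzius cells, the earliest cortical neurons, fell, while no list of cortical layer genes was called by camera. In the Cajal-Retzius list RELN, LHX1 (-1.26), EBF3 (-0.60) and LHX5 (-0.40) were lower among 6 tested members, also when adjusted over the list alone, with a median of -0.50. LHX1, EBF3 and LHX5 were low, at 4.49, 4.03 and 4.29 CPM in control and 1.87, 2.65 and 3.24 CPM in knockdown. The cells that expressed these genes were not resolved. The edgeR call of LHX5 was lost without control replicate 1 (adjusted p = 0.113) or 2 (0.122) and without knockdown replicate 2 (0.16) or 3 (0.144). In the DESeq2 Wald test EBF3 lost its call (adjusted p = 0.0563), as did LHX5 (0.197), whose call was also lost in limma-voom (0.0507), with no low-count filter (0.0592) and after removal of the length and GC trend (0.082). Camera called the list at adjusted p = 0.0224, and lost it at adjusted p = 0.208 with an estimated correlation, without control replicate 3 (adjusted p = 0.0598), without knockdown replicate 1 (adjusted p = 0.0758) and on log2(TPM + 1) (adjusted p = 0.0894). Of 10 deep layer genes FOXP2 (-1.32), NR4A2 (-1.67) and TLE4 (-0.48) fell and NEUROD6 rose from 0.368 to 2.45 CPM. Of 8 upper layer genes FRMD4B (0.53), POU3F2 (0.28), LHX2 (0.33) and CUX2 (0.48) rose and none fell, though on log2(TPM + 1) the calls of POU3F2 (adjusted p = 0.126) and CUX2 (0.0852) were lost. Ventral telencephalic and interneuron genes were plentiful in both groups, GAD1 at 207 and 204 CPM (not called, but lower on log2(TPM + 1) at adjusted p = 0.00115) and DLX1 at 199 and 173 CPM, and 5 of 14 rose while 6 fell. LHX6 rose from 8.98 to 18.8 CPM and SST, which encodes somatostatin, from 0.762 to 4.88 CPM, whereas SP8 fell from 44.8 to 24.2 CPM. Among telencephalic patterning genes 5 of 9 rose and 2 fell. NR2F1 and NR2F2 led the rises, and EMX1, a dorsal cortical factor, fell from 1.12 to 0.203 CPM. Camera called neither the deep layer list (adjusted p = 0.238), nor the upper layer (0.155), interneuron (0.863) or patterning lists (0.155), and for each of these the counts were the same when adjusted over the list alone.

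Genes of the radial scaffold moved in both directions. Of 29 apical junction and polarity genes 12 were higher and 8 lower (12 and 9 when adjusted over the list alone), with a median of 0.09 that was 0.15 with the length and GC trend removed and -0.10 on log2(TPM + 1). CRB1, a determinant of apical identity, rose by 0.84 and NECTIN3, a junctional adhesion protein, by 0.62, whereas CTNNA2, the neural alpha-catenin, fell by 0.69 and CDC42, in the lowered part of chromosome 1, by 0.49. CDH2, which encodes N-cadherin and was named after its values were seen, fell by 0.24 from 238 to 202 CPM. Of 23 cytoskeletal genes of the radial fibre 6 were higher and 11 lower. EZR and MSN, which link membrane to actin, rose by 0.72 and 0.42, KIF11 rose by 0.80, and MAP1B, a neuronal microtubule protein, fell by 0.49. Basement membrane and matrix genes had 2 of 23 members higher and 9 lower. The members that rose were SPARC, from 67.6 to 137 CPM, and LAMB2, from 16.1 to 26.2 CPM, while TNC and VCAN fell by 1.06 and 0.41 and AGRN, in the lowered part of chromosome 1, by 0.59. Of 20 integrin and focal adhesion genes 7 rose, ITGB1 by 0.43 and TLN1 by 0.53 among them, and 7 fell. Camera called none of these lists (adjusted p = 0.517, 0.783, 0.32 and 0.953 in the order given), and counts adjusted over the list alone were the same for the last 3.

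Sterol synthesis genes were mostly higher and glycolytic genes mostly lower. In fatty acid oxidation 7 of 20 genes were higher and 2 lower. ETFB, the beta subunit of the flavoprotein that takes electrons from acyl-CoA dehydrogenases, rose from 21.1 to 77.2 CPM (1.87 ± 0.06 SE), SLC25A20, the carnitine carrier, by 0.81, HADHA by 0.46 and HADHB by 0.49. Fatty acid synthesis had 8 of 22 higher and 6 lower (9 and 7 when adjusted over the list alone), with SCD, ELOVL5 and FADS1 higher by 0.39, 0.40 and 0.33 and SCD5 lower at -0.59. Camera called neither (adjusted p = 0.132 and 0.517). In sterol synthesis 17 of 24 genes were higher and 3 lower, with a median of 0.20 (0.13 under library totals alone and 0.02 on log2(TPM + 1)) and, among them, HMGCS1 from 2052 to 2702 CPM, MSMO1 from 480 to 638 CPM and IDI1 from 774 to 1015 CPM. Camera called the sterol list at adjusted p = 0.0103, and it was lost at adjusted p = 0.133 with an estimated correlation and on log2(TPM + 1) (adjusted p = 0.0784). The list of glycolysis and hypoxia genes had 18 of 25 members lower and 2 higher (19 and 2 when adjusted over the list alone), with a median of -0.33. PFKP, a phosphofructokinase, fell from 67.2 to 33 CPM and LDHA, lactate dehydrogenase, from 93.5 to 65.1 CPM, and ENO1 and SLC2A1, both in the lowered part of chromosome 1, fell by 0.86 and 0.95. Camera called it at adjusted p = 8.04e-06 (adjusted p = 0.0528 with an estimated correlation), and without the genes of shifted segments at adjusted p = 1.68e-05. In the fatty acid oxidation and sterol lists the counts adjusted over the list alone were the same.

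Stress response genes rose in part. Of 22 genes of the endoplasmic reticulum and integrated stress responses 18 were higher and 1 lower, the same numbers when adjusted over the list alone, with a median of 0.33 that was 0.15 on log2(TPM + 1). DDIT3, which encodes CHOP, rose from 73 to 131 CPM (0.84 ± 0.05 SE), PHGDH and PSAT1 of serine synthesis by 0.77 and 0.39 and SHMT2 by 0.45, and the gene that fell was SESN2 (-0.38), in the lowered part of chromosome 1. Camera called the list at adjusted p = 3.01e-06, which became adjusted p = 0.0946 with an estimated correlation. Interferon response genes were low, and 7 of 13 were higher and none lower, the same numbers when adjusted over the list alone, with a median of 0.35 that was 0.19 on log2(TPM + 1). IFIT1 rose from 8.4 to 19.6 CPM, MX2 from 1.01 to 4.03 CPM and IFI44L from 1.65 to 3.39 CPM. The camera call at adjusted p = 0.0196 became adjusted p = 0.286 with an estimated correlation. It was lost without control replicate 3 (adjusted p = 0.0647), without knockdown replicate 2 (adjusted p = 0.0511), with no low-count filter (adjusted p = 0.108) and after removal of the length and GC trend (adjusted p = 0.0553). Immediate early and dissociation genes had 8 of 18 lower and 3 higher, the same numbers when adjusted over the list alone. HSPA1A and HSPA1B, which encode inducible HSP70 and are near-identical copies of uncertain separation, fell by 1.52 and 0.47 and the members that rose included ATF3, by 0.51, and camera did not call the list (adjusted p = 0.132).

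Signalling genes shifted gene by gene, with no list called by camera. Of 19 Notch genes 8 were higher and 1 lower, HES5, NOTCH3 and JAG1 rising by 0.69, 0.50 and 0.42 and DTX1 falling by 0.43 (camera adjusted p = 0.366). Of 20 Wnt genes 5 were higher and 4 lower, with the receptor FZD5 up by 0.69 and the secreted inhibitor FRZB and the Wnt export protein WLS down by 0.95 and 1.03 (0.783). Of 12 BMP and TGF-beta genes 6 were lower and 1 higher, SMAD7 and TGFB2 falling by 0.95 and 1.12 and BMP7 rising by 0.94 (0.198). Of 12 YAP and TAZ targets and factors 6 were lower and 3 higher, with F3 down by 0.86 and AXL and YAP1 up by 1.12 and 0.50 (0.517). Oxidative stress and ferroptosis genes had 5 of 17 higher and 5 lower (5 and 7 when adjusted over the list alone), with SLC7A11, the cystine transporter, up by 0.75 and PRDX1, in the lowered part of chromosome 1, down by 0.33 (0.827). Of 12 mitochondrially encoded genes MT-COX1, MT-COX3 and MT-ND1 were higher by 0.42, 0.21 and 0.15 (0.596). MT-ND1 lost its edgeR call without control replicate 2 (adjusted p = 0.0881) or 3 (0.0692) and without knockdown replicate 1 (0.0543) or 2 (0.0585), under library totals (0.151) and on log2(TPM + 1) at -0.01 (0.801), where MT-COX3 lost it too (0.381). After removal of the length and GC trend MT-COX3 (0.222) and MT-ND1 (0.773) were not called. MT-ATP6, not called in the edgeR test, passed as higher without control replicate 1 (0.000317) and with the replicate number as a block (0.0107). For the other lists of this paragraph counts adjusted over the list alone were the same.

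Markers of the other cell type lists moved separately, and many of them were low. None of the 8 endothelial genes could be tested, and of the microglial and blood genes only AIF1 could, which rose from 2.93 to 10.5 CPM. SOX10, CSPG4 and MBP of the oligodendrocyte list were lower and under 5 CPM. CSPG4 lost its edgeR call without knockdown replicate 2 (adjusted p = 0.0615) in the DESeq2 test (0.117) and after removal of the length and GC trend (0.0809). MBP lost it without control replicate 1 (0.0939), 2 (0.057) or 3 (0.0523), without knockdown replicate 1 (0.12) or 3 (0.135), in the DESeq2 test (0.185), with no low-count filter (0.0541) and after removal of the length and GC trend (0.243). LUM, a collagen-binding proteoglycan of mesenchyme, rose from 0.484 to 6.81 CPM, PDGFRB from 10 to 16 CPM and COL5A1 from 3.7 to 7.17 CPM. PMEL and MITF of the retinal list were higher, MITF from 1.67 to 3.06 CPM. CLU, GJA1 and APOE of the astroglial list rose by 0.82, 1.42 and 0.47, and SLC1A2 and AQP4 fell by 0.34 and 1.09. BMP7 and RSPO3 of the choroid plexus and hem list rose by 0.94 and 1.52 and WNT2B fell by 0.50. DNMT3B and LIN28A (the last in the lowered part of chromosome 1) of the pluripotency list fell by 0.74 and 0.88. No member of the diencephalon, midbrain and hindbrain list passed the test among 4 tested, TCF7L2 being nearest with a log2 fold change of 0.22 (edgeR adjusted p = 0.0531, but 0.019 without control replicate 1, 0.0264 without knockdown replicate 1, 0.0372 with no low-count filter and 0.0161 after removal of the length and GC trend). KRT18 and KRT8 of non-neural epithelium were higher, both under 4 CPM, KRT8 losing its call without control replicate 3 (adjusted p = 0.0772) and in the DESeq2 test (0.0753), and KRT18 in the DESeq2 test (0.052). Among muscle genes DES and MYH3 were lower and TNNT1 and TTN higher, but all 4 lost the call in the DESeq2 test (adjusted p = 0.0792, 0.0607, 0.155 and 0.157). MYH3 also lost it without control replicate 3 (0.125) or knockdown replicate 2 (0.059), and TNNT1 without control replicate 1 (0.0653) or 3 (0.0556) or knockdown replicate 2 (0.162). TTN lost it without control replicate 1 (0.059), 2 (0.0695) or 3 (0.0581) without knockdown replicate 1 (0.0706) or 3 (0.111) and under library totals (0.0872). LPL, a lipoprotein lipase, was the 1 adipogenic gene of 6 tested that passed, from 2.45 to 5.01 CPM. CEBPA passed as lower without control replicate 3 (adjusted p = 0.0373), under library totals (0.0436) and on log2(TPM + 1) (0.00996), and LIPE as higher after removal of the length and GC trend (0.0188). On log2(TPM + 1) AQP1 of the choroid plexus list (0.0117) and NANOG of the pluripotency list (0.0326) also passed as lower. Camera called none of the lists with 5 or more tested members here: oligodendrocyte (adjusted p = 0.463), mesenchyme (0.135), astroglia (0.32), choroid plexus (0.783), pluripotency (0.238), epithelium (0.32) and adipogenesis (0.517). Adjusting over each list alone changed none of their counts.

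Position along the genome, examined after the fold changes had been seen, marked out 3 segments. Median log2 fold changes of expressed genes were taken in 412 bins of 5 Mb with at least 10 such genes each, and 14 bins had a median of at least 0.35 in size. The number of segments depends on that limit, since the bins at 30 to 35 Mb of chromosomes 5 and 18 fell just short of it, at medians of -0.346 over 16 genes and -0.346 over 10 genes. Of the 14 bins, 11 were contiguous and formed the first 55 Mb of chromosome 1, where 436 expressed genes had a median of -0.46 (quartiles -0.67 and -0.27) and 94.7% were lower. A single bin at 200 to 205 Mb of chromosome 1 held 35 expressed genes with a median of -0.85, and 100% were lower. The bins from 0 to 10 Mb of chromosome 5 held 30 expressed genes with a median of 0.68, of which 93.3% were higher. The 10 expressed genes in the 5 Mb that follow the chromosome 5 segment had a median of -0.01, the 32 within 5 Mb of either side of the 200 to 205 Mb segment a median of 0.09, and the 9 in the 5 Mb after the first 55 Mb of chromosome 1 a median of -0.49. In the segments 444 of 591 tested genes (75.1%) were called lower, against 2965 of 12877 (23.0%) elsewhere. Without the segment genes 6407 genes were called, 3293 higher and 3114 lower, and 484 changed at least 2-fold. The 9 expressed genes after the first 55 Mb of chromosome 1 were too few to form a bin, so that stretch was not left out.

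**Figure D3:**
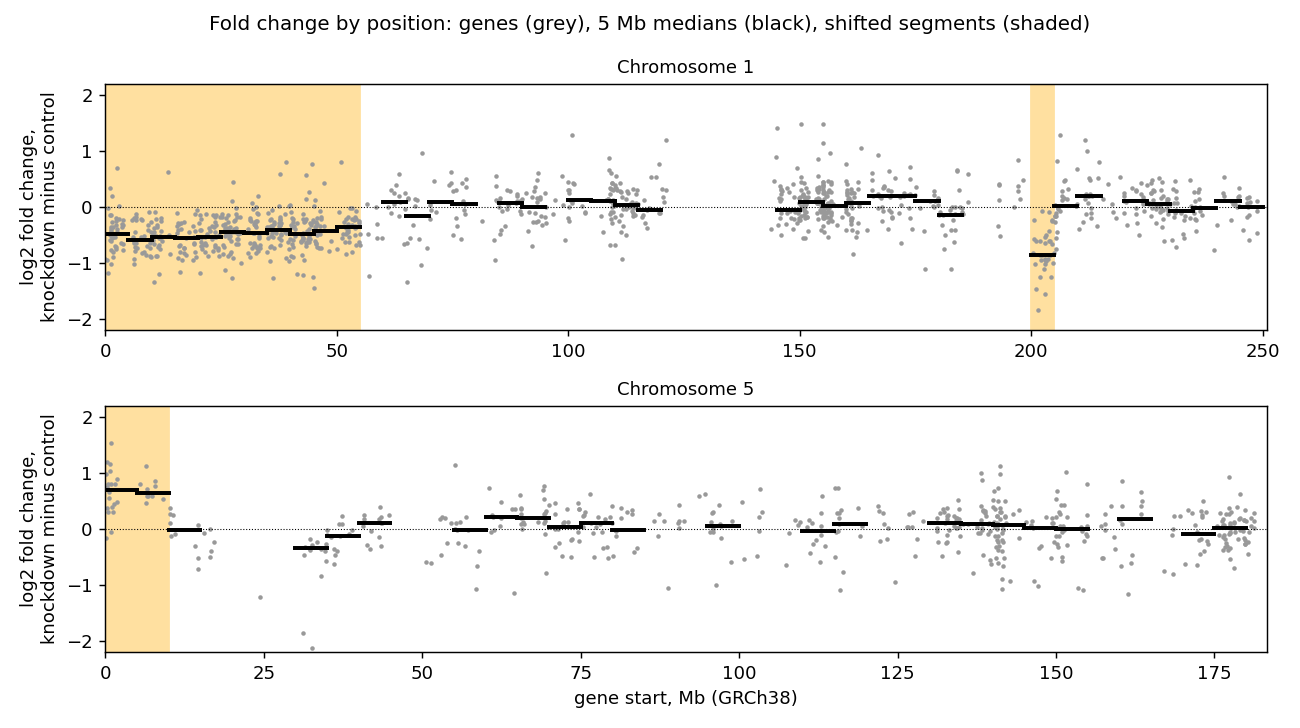
Log2 fold change (vertical axes, knockdown minus control) against gene start in Mb on GRCh38 (horizontal axes) for genes with a mean of at least 4 CPM on chromosomes 1 and 5; black bars are medians of 5 Mb bins, shading marks the 3 shifted segments, and 2 genes on each chromosome lie outside the vertical range. The first 55 Mb of chromosome 1 sit at a median of -0.46 and the first 10 Mb of chromosome 5 at 0.68.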

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

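The tests without segment genes, on log2 CPM by limma-trend and with the length and GC trend removed were chosen after seeing the results. FABP7 kept its direction and call under all 18 alternatives, from -7.64 to -7.40. The count of changed genes stayed between 5550 and 7224 and was 5888 to 6983 when 1 library was left out, against 6966. The count with at least 2-fold change was 187 with at least 10 CPM in 3 libraries, where fewer genes were tested, and 211 on log2(TPM + 1), against 531, and 567 to 584 when 1 library was left out. Lists called by camera numbered 0 with an estimated correlation and 29 in fry, against 11, and 8 to 12 when 1 library was left out. Samples of the same replicate number are not stated to share more than that number. Their deviations from group means correlated at 0.174, 0.0699 and 0.0703 across 11245 genes for replicates 1, 2 and 3. Replicate 1 correlated best with its own number in both groups, replicates 2 and 3 did not, and a shared batch was not excluded. The replicate number as a block gave 7114 changed genes, 533 of at least 2-fold and 11 lists. The split of higher and lower genes was 3557 and 3409 under TMM, 2653 and 4390 under library totals alone and 1475 and 5694 on log2(TPM + 1). Of 3147 values of 179 named genes under the alternatives 3053 kept direction and call, 63 lost the call, 13 gained it and 18 turned direction. Of 218 values of called lists 197 kept both and 21 lost the call.

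Values that turned direction were small. Under library totals DPPA4 was -0.0291. On log2(TPM + 1) FABP5 was -0.0192, COL1A2 -0.0301, DPPA4 -0.132, MT-ND1 -0.0149 and MT-ATP6 -0.0173. After removal of the length and GC trend FABP5 was -0.000291, BEST1 0.0581, DPPA4 -0.0210, MT-ATP6 -0.0445 and GAD1 0.00999. With 1 library left out LHX9 ranged from -0.0719 to 0.0975, BEST1 from -0.180 to 0.129, PLIN1 from -0.0899 to 0.657, GAD1 from -0.0369 to 0.000469 and DPPA4 from -0.00683 to 0.0819. The cause was not tested. The alternative pseudocount was not run, as counts were present. Depth limits tests of genes near the floor of 3 counts per library, 0.188 to 0.217 CPM.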

Other observations

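The tests of random placement, of the length and GC trend on segments, of gene dose for p53 targets and of progenitor share were chosen after seeing the results. The 6 gene families described next were picked after their fold changes were seen, so their values are given without p-values for the families. Targets of fibroblast growth factor and ERK signalling fell while the receptor FGFR3 rose, with 12 of 17 lower and 1 higher and a median of -0.60. ETV1 fell from 43.4 to 11.3 CPM, DUSP6, a phosphatase that restrains ERK, from 8.47 to 2.25 CPM and the inhibitor SPRY2 from 27.0 to 16.0 CPM, while CCND1 was the member that rose (0.13). All 5 ZIC genes fell, ZIC1 from 224 to 49.4 CPM and ZIC2 from 40.9 to 13.3 CPM, with a median of -1.62.

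Of the other families, 10 of 14 protocadherin beta genes were higher and none lower, with a median of 0.71 that was 0.23 on log2(TPM + 1), with PCDHB2 from 26.9 to 58.4 CPM, in a cluster of similar genes whose separation is uncertain. Ribosomal protein genes had 53 of 79 members higher and 5 lower with a median of 0.27, which was 0.21 with the length and GC trend removed and 0.12 on log2(TPM + 1). Proteasome genes had 27 of 39 higher and 2 lower with a median of 0.16 that was -0.02 on log2(TPM + 1). Complex I genes had 24 of 37 higher and none lower with a median of 0.23, which was 0.14 with the length and GC trend removed and 0.09 on log2(TPM + 1). Of the 5 further genes near silence in 1 group, 3 were higher in knockdown: CXCL11, a chemokine, with 3 counts against 139 (ratio 46.4, 95% counting interval 15.6 to 228), RUBCNL with 3 against 92 (30.7, 10.2 to 152) and NMRK2 with 3 against 85 (28.4, 9.39 to 140). The 2 higher in control were REG1A with 35 counts against 1 (34.9, 5.87 to 1419) and CTCFL, a germline paralog of CTCF, with 50 against 3 (16.6, 5.38 to 83.4).

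Among the 10 splits of the 6 libraries into groups of 3, the real one was the only one of 10 (1 split) to reach its own count of 6966 genes, the highest other being 0. The same held for 531 genes of at least 2-fold (1 split, highest other 0) and for 11 lists (1 split, highest other 10). With 10 splits there are too few for a share under 0.05, and chance as the cause was neither excluded nor shown.

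For the shifted chromosome segments 3 explanations were weighed, of which random placement gave at most 2 shifted bins in 1000 shuffles of fold changes over genes, and 0 shuffles reached 14. Length and GC content did not account for the segments, since the first 55 Mb of chromosome 1 stayed at a median of -0.42 (-0.418092) after the trend was removed. A difference in copy number between both cell lines predicted, before the test, that weakly expressed genes not used to find the segment would lie lower too, and 76 such genes had a median of -0.49 (-0.493755) against -0.11 elsewhere. The values of the first 55 Mb of chromosome 1 are consistent with a lower gene dose in the knockdown line than in the control line, log2 of 2 copies over 3 being -0.58. The segment at 200 to 205 Mb had a median of -0.85 and quartiles of -1.01 and -0.59. Its median lay between the ratio of 2 copies over 3 and the 2-fold fall of 1 copy over 2. The chromosome 5 segment had a median of 0.68, log2 of 3 copies over 2 being 0.58. However, the 7 weakly expressed genes of the chromosome 5 segment had a median of only 0.09. DNA was not measured, and a regional change of expression was not tested.

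The fall of p53 targets was weighed against 3 explanations. Gene dose of the members themselves could bear on PHLDA3 alone, the 1 of 18 in a segment. Without segment genes the median was -0.48 (-0.482987), but leaving out 1 member could hardly move it. Indirect effects of segment genes on p53 targets were not tested. The length and GC trend did not account for the fall, at -0.51 (-0.51088). A further list of 27 p53 targets outside the fixed list, predicted before the test to be lower if p53 activity was lower, had 16 of 26 lower and 1 higher with a median of -0.25 (-0.246066) and camera p of 5.18e-05, and p of 0.0133 with an estimated correlation. These values are consistent with lower p53 transcriptional activity in the knockdown line, which 1 line per group does not tie to FABP7.

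The rise of G2/M genes beside the fall of neuronal genes was weighed against 2 explanations. A higher share of progenitor cells as the whole cause would raise S phase and radial glial genes as much as G2/M genes, but G2/M genes exceeded S phase genes by a median of 0.77 (0.765914, 95% bootstrap interval 0.593 to 0.933) and radial glial genes by 0.81. The length and GC trend did not account for the neuronal fall, as the pan-neuronal median was -0.47 (-0.470314) after its removal. Cell composition itself was not measured here.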
